A study of Mus musculus with 5 samples.

How the data were processed

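RNA sequencing was made from Ba/F3 cells, a mouse pro-B cell line that depends on interleukin-3, after infection with lentivirus. There were 5 libraries, 1 for each of 5 groups, labelled PMSCV, S_PXT1, S_PXT1_K118R, WT and WT_K118R. The labels do not spell out the names S and WT, and they are used here as given. No group had a replicate, so no test across libraries was made and no p-value is given.

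The authors deposited 1 table with raw read counts and FPKM values (counts scaled by gene length and library size) side by side for each library, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1 and FastQC, with no role or order. The counting tool, the strand setting, the genome build and the annotation are not given in the sources used here. The table lists 50867 genes by human identifiers, human symbols and human chromosome positions, although the labels give mouse cells. Genes are named here by those human symbols, and a count is the number of reads that the authors assigned to a human gene model. How far a mouse transcript is counted on such a model depends on its sequence, so levels are compared between libraries and not between genes. Of the deposited FPKM values above 0, at least 99.98% of those compared between libraries equalled the count of the same row divided by 1 length per gene and 1 factor per library, within 0.01 on the log2 scale. The counts were therefore used, and FPKM entered as an alternative. There were 0 value columns without a library.

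The total count was 266905 in PMSCV, 259047 in S_PXT1, 250409 in S_PXT1_K118R, 351693 in WT and 347661 in WT_K118R. A single count corresponded to between 2.92 and 3.93 CPM (counts scaled to the library size). The floor set by a count of 0 was 3 counts, between 8.77 and 11.8 CPM. Library sizes were scaled by the trimmed mean of M values in edgeR 4.0.16 under R 4.3.3. The log2 ratio of 2 libraries was taken on CPM with a pseudocount of 1 CPM, so it understates the difference of low genes. Genes entered at a mean of at least 1 CPM over the 5 libraries. Folds of single genes and of summed lists were taken on the scaled counts without the pseudocount, with the exact 95% interval of the ratio of 2 counts. Levels of single genes carry exact Poisson intervals. Both kinds of interval cover counting error only, and reads without molecular identifiers are not independent molecules. A fold against a library with 0 counts was computed against the floor of 3 counts in that library and is written as "at least".

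A gene was counted as higher or lower at a 2-fold difference. Beside these counts stands the number that counting error alone gave, as the mean of 100 sets of Poisson draws around each gene's pooled rate in the 2 libraries. The comparisons were S_PXT1 over PMSCV, WT over PMSCV, S_PXT1 over WT, S_PXT1_K118R over S_PXT1, and WT_K118R over WT. For every library in turn, genes at least 2-fold above or below each of the other 4 were counted. The K118R ratios in the S_PXT1 and WT backgrounds, which share no library, were correlated across genes, and so were the S_PXT1 over WT ratios with and without the substitution.

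The median log2 ratio of each of 28 gene lists was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a test. Lists with fewer than 5 entering members have no percentile. Of the 637 mouse symbols in the lists, 621 were matched to a human symbol in the table. Summed counts and summed folds of a list cover all its matched members, also those that did not enter. The random lists, bins and draws used fixed seeds. Genes named in the text had the 10 highest or 10 lowest ratios per comparison, among symbols on a single row with a mean of at least 5 CPM. Names in the mouse style for unnamed models and pseudogenes, and some clone names, were left out. Human pseudogenes such as RPL7P14 and other clone names passed this filter. Also named were the 2 to 4 list members with the largest ratios and the genes of the constructs. For the correlations and single-library counts, the 10 genes with the largest smaller ratio were named. The comparisons, filter, lists and naming rule were fixed before the data were examined. A further gene of the constructs and some genes that this rule names are not reported here.

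Chosen after seeing the data were the counts at a mean of at least 20 or at least 100 reads, the genes named from those counts, the limit to ratios whose interval excludes 1, the limit to symbols known in mouse, the summing of overlapping gene models on 1 strand to a single locus, and 4 further lists of marker genes. Any other gene chosen after its values were seen is marked as such. Alternatives that need replicates did not apply. The alternatives chosen before that were pseudocounts of 0.1 and 5 CPM, no filter, a filter at a mean of 5 CPM, size factors from DESeq2 1.42.0, thresholds of 1.5-fold and 3-fold, named genes alone, and FPKM. The file gives no biotype, so genes with clone names or no name were left out for the named set. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

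The ratios and intervals were tested on simulated counts drawn from the mean levels and library sizes, with 200 genes changed. For S_PXT1 over PMSCV, among the 1547 genes with a mean of at least 20 reads, 100% of genes raised 4-fold and 94% of genes lowered 4-fold passed the 2-fold threshold, as did 0.594% of unchanged genes. Over all 13352 genes entering that comparison the shares were 94%, 48% and 37.7%.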

Results

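Gene expression was measured in 5 libraries of Ba/F3 cells, each infected with lentivirus carrying a different construct. The series title concerns a fusion oncogene of childhood leukaemia and the stability of its mRNA. The library labelled PMSCV names a retroviral vector and serves as the reference. The libraries labelled S_PXT1 and WT each have a counterpart labelled K118R, which names a lysine to arginine substitution. Each group held 1 library, so no difference below has a replicate check.

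The gene named in the construct labels gave no check of them. PXT1 (ENSG00000179165, chromosome 6, 36390551 to 36442889 in the coordinates of the table, whose build is not given in the sources used here) had 0 counts in all 5 libraries, which allows up to 3 counts in each. For this reason each group is called here the library labelled with its name. STK38L (chromosome 12, 27243968 to 27325959), a kinase of the NDR family, had 4 counts in PMSCV, 7 in WT, 3 in WT_K118R and 0 in S_PXT1 and S_PXT1_K118R.

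The libraries differed in how many genes they held. PMSCV, WT and WT_K118R had at least 1 count for 11492, 11712 and 11504 genes. S_PXT1 and S_PXT1_K118R had counts for 7393 and 7044 genes. Totals ran from 250409 counts in S_PXT1_K118R to 351693 in WT, and thinned to 250409 counts PMSCV still held 11284 genes. All genes of the mitochondrial chromosome, ribosomal RNAs included, took 1.25% of the counts in PMSCV, 1.30% in WT and 1.25% in WT_K118R, against 0.658% in S_PXT1 and 0.571% in S_PXT1_K118R.

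**Figure D1:**
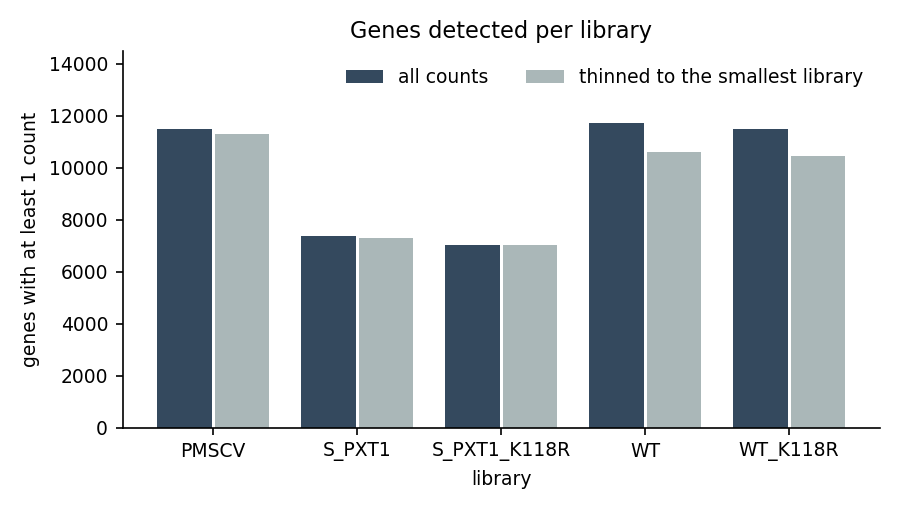
Number of genes with at least 1 count (vertical axis) in each library (horizontal axis), with all counts (dark bars) and as the mean of 10 draws thinned to 250409 counts (light bars). The libraries labelled S_PXT1 and S_PXT1_K118R hold 7305 and 7044 genes after thinning, and the lowest of the other 3 holds 10451.

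The library labelled S_PXT1 was compared with PMSCV to describe expression with the S_PXT1 construct against the vector. Keratin and immunoglobulin genes counted with PMSCV were at or near 0 with S_PXT1, mitochondrially encoded genes were lower, and CITED2, LDB1 and GATA2 were higher. CITED2 (ENSG00000164442, chromosome 6, 139371807 to 139374620), a transcriptional coregulator, had 1291 counts with S_PXT1 against 450 with PMSCV, 3.15-fold higher (95% interval 2.82 to 3.51). LDB1 (ENSG00000198728, chromosome 10, 102107560 to 102120453), a cofactor of LIM-domain and GATA transcription complexes, was 3.54-fold higher (2.72 to 4.66), and GATA2 (ENSG00000179348, chromosome 3, 128479427 to 128493185), a transcription factor of blood progenitors and mast cells, was 2.31-fold higher (1.80 to 2.97). The 13 mitochondrially encoded protein genes summed to 1267 counts against 2513, a fold of 0.55 (0.52 to 0.59). Their sum was 8936.5, 10832.3 and 10411.5 CPM in PMSCV, WT and WT_K118R, against 4939.5 and 4686 in S_PXT1 and S_PXT1_K118R. The number of genes detected divides the libraries in the same way. An effect of the construct on these genes therefore cannot be told apart from anything else the S_PXT1 and S_PXT1_K118R libraries share.

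IGHG2, an immunoglobulin heavy chain, had 107 counts with PMSCV and 0 with S_PXT1, at least 32.5-fold lower, and IGHG1 had 310 against 1, a ratio of 283 (50.4 to 11204). KRT17 and KRT5, keratins of squamous epithelium, had 78 and 76 counts with PMSCV and 0 with S_PXT1, at least 23.7-fold and 23.1-fold lower. STEAP2 and KRT6A were each at least 17.6-fold lower, and KLK3, a prostate protease, was at least 15.5-fold lower. IGKC had 204 counts against 1, a ratio of 186 (33.0 to 7385). SLC25A4, the ADP/ATP carrier of mitochondria, and PRUNE2 were at least 12.2-fold and 11.9-fold lower. The fixed list of fibroblast, endothelial and epithelial markers had a median log2 ratio of -3.57 over 14 entering members, at the 0.00 percentile of random lists, -1.44 with members at 0 counts set to their bound and -1.87 with FPKM. Of its members 10 were lower and 1 higher. The median was -0.72 over the 5 members with a mean of at least 20 counts, and the summed fold was 0.44 (0.38 to 0.52), 232 counts against 573. COL1A1, a fibrillar collagen named after its values were seen, had 100 counts against 162, whereas COL1A2 had 3 against 90.

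The high end rested on smaller counts. SENP3-EIF4A1, a model that joins neighbouring genes, had 28 counts with S_PXT1 and 0 with PMSCV, at least 10.2-fold higher, but its direction was opposite when overlapping models on 1 strand were summed. ATP6V1G2-DDX39B was at least 8.40-fold higher, but its log2 ratio was 0.53 when such models were summed. USP3 was at least 6.58-fold higher, EIF2B3 at least 5.85-fold and TAF12 at least 5.48-fold. ARHGEF6 had 48 counts against 1, a ratio of 52.6 (9.0 to 2121), but it was low in PMSCV alone, with 38 to 48 counts elsewhere. IRF2, TAF6, PLCB3 and RP11-159G9.5 had 8 or 9 counts against 0. PLCB3 was also at 0 in PMSCV alone, with 8 to 22 counts elsewhere.

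Among the 505 genes with a mean of at least 100 counts, 12 were higher and 7 lower by 2-fold, and 96.2% lay within 2-fold. Their median log2 ratio was 0.28, against which the folds of such genes can be read. PSME3, a proteasome activator subunit, was 4.60-fold higher (3.93 to 5.41), but it was low in PMSCV alone, at 690 CPM against 2907 to 3173 CPM elsewhere. CPSF6, an mRNA cleavage factor, was 4.65-fold higher (3.16 to 7.02), and the histone variant H2AZ1 3.54-fold (3.05 to 4.12). CBX1, a heterochromatin protein, was 3.48-fold higher (2.57 to 4.77) and SMARCC2, a chromatin remodelling subunit, 2.79-fold (2.15 to 3.64). KHDRBS1, G3BP2, SRSF10 and BIRC6 were between 2.01-fold and 2.19-fold higher. SERBP1, an RNA-binding protein, was 8.35-fold lower (7.32 to 9.56), RPN2 had 6 counts against 127, and HMGB1, TUBA1C, MT-CYB and MT-CO1 were between 2.06-fold and 3.08-fold lower. TFRC, the transferrin receptor, had 132 counts with PMSCV and 5 with S_PXT1, 24.1-fold lower (10.1 to 75.4).

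Gene groups differed in the same comparison. The same 13 genes had a median log2 ratio of -0.75 (0.00 percentile), with 4 members lower and 0 higher. The 29 cytosolic ribosomal protein genes had a median of -0.61 (0.01 percentile) with 8 lower, among them RPL3 with 31 counts against 106, but their summed counts were 1.18-fold higher (1.12 to 1.24), with RPLP0 at 2712 against 2032. Heat shock chaperones had a median of -0.62 (0.98 percentile), -0.37 with zeros at their bound, with 6 of 16 lower, and a summed fold of 0.92 (0.84 to 1.01). The list of RNA stability and AU-rich element regulators had a median of 0.25 (97.7 percentile), 0.11 with zeros at their bound, although 3 of its 29 members were higher and 7 lower. PABPC1, the poly(A)-binding protein, which was named after its values were seen, had 8495 counts against 6150 and made up much of the summed fold of 1.31 (1.29 to 1.34). Mast cell and basophil markers had a median of -3.02 (1.12 percentile), 0.00 with zeros at their bound, while their summed counts were 1.88-fold higher (1.49 to 2.38). GATA2 supplied all 202 of these counts with S_PXT1 and 96 with PMSCV.

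Over all 13352 genes entering, 1154 were higher and 5854 lower by 2-fold with S_PXT1, with a median log2 ratio of -0.56. Counting error alone gave means of 1999.6 higher and 2231 lower genes, and the interval excluded 1 for 115 higher and 979 lower genes. Among the 1547 genes with a mean of at least 20 counts, 54 were higher and 121 lower, against 15.7 from counting error.

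**Figure D2:**
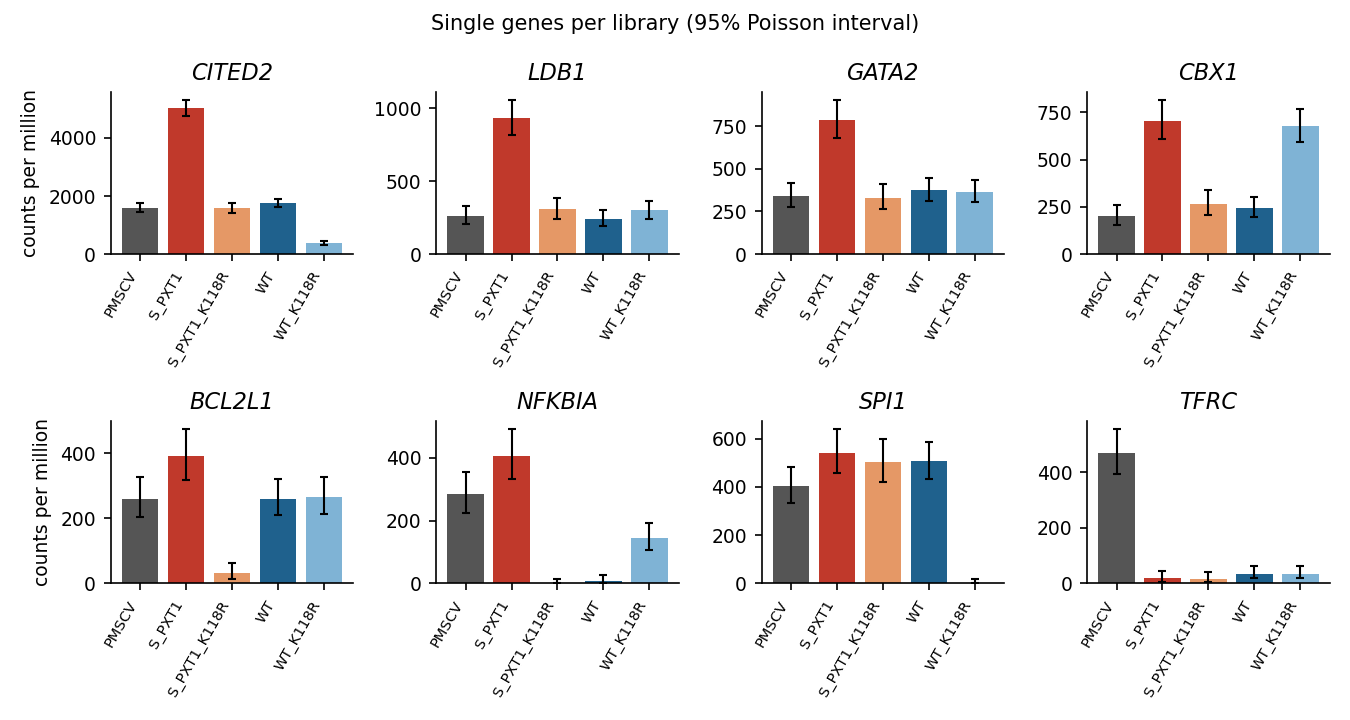
Normalised read counts (CPM) (vertical axes, starting at 0) of 8 genes in the 5 libraries (horizontal axes), with exact 95% Poisson intervals that cover counting error only. CITED2, LDB1 and GATA2 stand above the other 4 libraries with S_PXT1, SPI1 is near 0 with WT_K118R (1 count), and TFRC is high with PMSCV alone (132 counts).

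The library labelled WT was compared with PMSCV in the same way. CRNN, S100A9 and SPINK5 were higher with WT, interferon-stimulated genes were lower, and 98.6% of genes with a mean of at least 100 counts lay within 2-fold. CRNN, a cornified-envelope gene, had 69 counts with WT and 0 with PMSCV, at least 18.9-fold higher. S100A9, a neutrophil and epithelial calcium-binding protein, had 40 counts against 0, SPINK5 was at least 7.40-fold higher, and MAL and PDSS2 at least 5.21-fold. The 18 interferon-stimulated genes entering had a median log2 ratio of -1.69 (0.01 percentile), 0.00 with zeros at their bound, with 12 lower and 0 higher. All 27 matched members of the list summed to 19 counts against 61, a fold of 0.26 (0.14 to 0.43). Squamous and smooth muscle lists, written after the ratios were seen, summed to 1413 and 385 counts with WT against 471 and 103 with PMSCV. The source of these tissue-type reads was not tested. For these lists an effect of the WT construct cannot be told apart from other differences between the libraries.

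SENP3-EIF4A1 was at least 18.1-fold higher with WT, and PLCB3, PLK4 and VPS29 each at least 6.03-fold higher. PLCB3 and VPS29 were at 0 counts in PMSCV alone. MT-ND4, a subunit of respiratory complex I, had 625 counts against 3, a ratio of 171 (58.4 to 833). Its neighbour MT-ND4L went the other way, with 1 count against 103, a ratio of 125 (22.0 to 4994). At the low end NDUFAB1, a mitochondrial acyl carrier protein, was at least 12.6-fold lower, ZDHHC6 at least 9.73-fold, PDCD5 at least 9.32-fold and SKAP2 at least 8.51-fold lower. TBP, the TATA-binding protein, had 12 counts with PMSCV and 0 with WT, and BLOC1S5-TXNDC5, TTC7B, CHI3L1 and BSCL2 had 11 to 15 against 0. For MT-ND4L and BLOC1S5-TXNDC5 the direction was opposite when overlapping models on 1 strand were summed, and the log2 ratio was then 2.28 for MT-ND4, 0.10 for SENP3-EIF4A1 and -0.04 for BSCL2.

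Among well-covered genes PSME3, low in PMSCV alone, was 4.21-fold higher with WT (3.61 to 4.94). CPSF6 was 4.09-fold higher (2.80 to 6.14) and TRA2B, a splicing regulator, 4.01-fold (3.29 to 4.92). YTHDF3, a reader of methylated mRNA, was 3.19-fold lower (2.38 to 4.33), HMGB1 3.08-fold (1.97 to 4.96) and RHOA 2.02-fold (1.66 to 2.47). NFKBIA, the inhibitor of NF-kB, had 3 counts with WT against 80 with PMSCV, and TFRC had 12 against 132, 13.4-fold lower (7.41 to 26.5). Unfolded protein response chaperones had a median of -0.52 (0.39 percentile), -0.47 with zeros at their bound, with 4 of 17 lower. Cholesterol synthesis genes had a median of -0.64 (1.32 percentile), -0.44 with zeros at their bound, with 7 of 19 lower and 1 higher. ERK-induced genes had a median of 0.44 (98.2 percentile), 0.00 with zeros at their bound, with DUSP5 at 17 counts against 3. Neutrophil and monocyte markers had a median of 0.83 (97.3 percentile), 0.00 with zeros at their bound, with 5 of 10 higher, and summed to 68 counts against 14, of which S100A9 supplied 40 and 0.

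With WT, 2710 genes were higher and 3092 lower than with PMSCV by 2-fold, against 2379 and 2209.9 from counting error alone. The interval excluded 1 for 193 higher and 304 lower genes. Among genes with a mean of at least 20 counts 42 were higher and 41 lower, against 8.42 from counting error.

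The libraries labelled S_PXT1 and WT were compared directly. KRT13, KRT4, KLK3 and IGHG1, counted with WT, were at or near 0 with S_PXT1, mitochondrially encoded genes were lower, and CITED2, LDB1 and GATA2 were again higher with S_PXT1. KRT13 and KRT4 had 266 and 262 counts with WT and 0 with S_PXT1, at least 66.5-fold and 65.5-fold lower. CITED2 was 2.86-fold higher (2.59 to 3.15), LDB1 3.84-fold (2.98 to 4.99) and GATA2 2.10-fold (1.68 to 2.65). These share the S_PXT1 library with the comparison against PMSCV and are not a separate measurement of it.

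SPRR3, KRT5, KRT6A, CRNN, IGHG2 and KLK3 were at least 15.5-fold to 31.3-fold lower with S_PXT1 than with WT, and SLC25A4 at least 14.8-fold lower. MT-ND4 had 2 counts against 625, a ratio of 234 (64.6 to 1940). At the high end NDUFAB1, TBP, PDCD5 and ZDHHC6 had 29 to 31 counts with S_PXT1 and 0 with WT, at least 12.9-fold to 13.8-fold higher. PDCD5 was at 0 in WT alone, with 16 to 29 counts elsewhere, and NDUFAB1 and TBP were at 0 in S_PXT1_K118R too. ATP6V1G2-DDX39B, SKAP2, DOCK2, SEC11C and EIF2B3 had 16 to 23 counts against 0. MT-ND4L had 63 counts against 1, and its direction was opposite when overlapping models were summed, with a log2 ratio of -2.85 for its locus with MT-ND4 and 0.02 for that of ATP6V1G2-DDX39B. Among well-covered genes YTHDF3 was 4.50-fold higher (3.39 to 6.04), CBX1 2.87-fold (2.21 to 3.77), RHOA 2.48-fold (2.04 to 3.02), H2AZ1 2.27-fold (2.01 to 2.56) and SMARCC2 2.21-fold (1.77 to 2.78). SERBP1 was 8.67-fold lower (7.61 to 9.91), TRA2B 4.35-fold (3.51 to 5.43) and TUBA1C 2.97-fold (2.80 to 3.16). NFKBIA had 104 counts against 3.

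The mitochondrially encoded protein genes had a median log2 ratio of -0.91 (0.00 percentile), with 6 of 13 lower and 1 higher, and their summed fold was 0.46 (0.43 to 0.49). Cytosolic ribosomal protein genes had a median of -0.67 (0.00 percentile), -0.64 with zeros at their bound, with 8 of 29 lower, and a summed fold of 0.93 (0.89 to 0.97). The p53 target list had a median of -2.78 (0.88 percentile) that lay near 0 with zeros at their bound, with 16 of 21 lower, among them PERP, a desmosomal gene of epithelia, at 0 counts against 22. Fibroblast, endothelial and epithelial markers had a median of -3.21 (0.01 percentile), -1.58 with zeros at their bound, with 10 of 14 lower, and -0.67 over the 5 members with a mean of at least 20 counts, with a summed fold of 0.52 (0.44 to 0.60). In all 1205 genes were higher and 5673 lower, with a median log2 ratio of -0.48, against 2023 and 2272 from counting error alone. The interval excluded 1 for 100 higher and 841 lower genes, and at a mean of at least 20 counts 47 were higher and 109 lower.

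**Figure D3:**
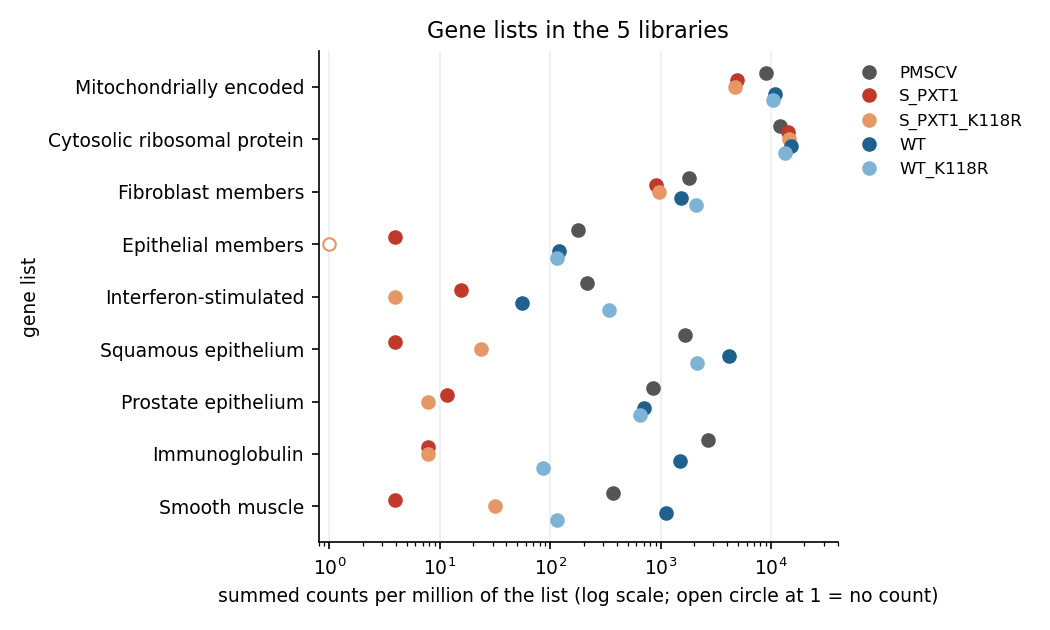
Summed normalised read counts (CPM) on a log axis (horizontal) of 9 gene lists or parts of lists (vertical) in the 5 libraries, 1 circle per library, with an open circle at 1 where no count was seen. The squamous, prostate, immunoglobulin and smooth muscle lists were written after the ratios were seen. Squamous genes hold 471 counts with PMSCV, 1413 with WT and 721 with WT_K118R, against 1 with S_PXT1 and 6 with S_PXT1_K118R.

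The substitution was examined in the S_PXT1 background by comparing S_PXT1_K118R with S_PXT1. CITED2, LDB1, GATA2 and BCL2L1 were lower with S_PXT1_K118R, and NFKBIA and YTHDF2 were near 0. CITED2 had 403 counts against 1291, 3.18-fold lower (2.84 to 3.56), LDB1 78 against 239, 3.04-fold lower (2.34 to 3.98), and GATA2 84 against 202, 2.38-fold lower (1.84 to 3.11). In S_PXT1_K118R these 3 genes stood at 1584, 307 and 330 CPM, and in PMSCV at 1600, 263 and 341 CPM. The S_PXT1 library is the same as in the comparisons with PMSCV and WT, so its high values are not measured again here. BCL2L1, which encodes the survival protein BCL-XL, had 8 counts against 100, 12.4-fold lower (6.05 to 29.5), and 73 to 90 counts in the other 3 libraries. NFKBIA had 0 counts against 104, at least 34.4-fold lower. It was also near 0 in WT, at 3 counts, with 80 in PMSCV and 49 in WT_K118R.

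Other genes at the low end were MT-ND4L, SLC7A6, SRRT, VRK1, DHX36, NDUFAB1, TXNDC5, TBP and UBN1. They had 30 to 63 counts in S_PXT1 and 0 in S_PXT1_K118R, at least 9.92-fold to 20.8-fold lower. NDUFAB1 and TBP were at 0 in WT too. At the high end SLC25A12, BCAP31, SLC25A4 and ARHGEF1 were at least 7.73-fold to 13.4-fold higher, and RGL1, TTC7B, IDH3G and MXI1 at least 4.37-fold to 6.39-fold higher. MT-ND4 had 203 counts against 2 and RBM4 90 against 1, ratios of 102 (28.0 to 851) and 90.8 (15.9 to 3624). For RBM4 and MT-ND4L the direction was opposite when overlapping models were summed, and the log2 ratio was then 1.65 for MT-ND4 and -1.59 for TXNDC5. Among well-covered genes 3 were higher and 13 lower. YTHDF2, a reader of methylated mRNA that promotes decay, was 32.7-fold lower (13.7 to 102), HSP90AA1 6.01-fold (3.58 to 10.7), and SERBP1 5.86-fold (4.21 to 8.33), while DYRK1A had 44 counts against 186. CPSF6 was 3.97-fold lower (2.72 to 5.92), SRSF10 3.06-fold (2.38 to 3.95) and CBX1 2.64-fold (1.99 to 3.54). MT-ND5, RAB11A and KHDRBS1 were between 2.01-fold and 2.42-fold lower. TUBA1C was 2.85-fold higher (2.68 to 3.04) and RPN2 had 110 counts against 6.

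Cytosolic ribosomal protein genes had a median log2 ratio of 0.40 (100 percentile), 0.29 with zeros at their bound, with 6 of 29 higher, among them RPL8 at 45 counts against 18 and RPL13 at 32 against 14. Their summed fold was 1.03 (0.99 to 1.08). The STAT5 and cytokine-induced list summed to 59 counts against 154, a fold of 0.39 (0.28 to 0.52), with a median log2 ratio of 0.00, and BCL2L1 supplied 8 and 100 of these counts. The ATF4 list had a median of 0.25 (98.2 percentile), 0.00 with zeros at their bound, and the BCL2 family list a median of -0.18 (2.38 percentile), 0.00 with zeros at their bound. In all 2032 genes were higher and 2344 lower, with a median of 0.00, against 1520.3 and 1552 from counting error alone. The interval excluded 1 for 153 higher and 170 lower genes, and at a mean of at least 20 counts 52 were higher and 74 lower, against 26.2.

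The substitution was examined in the WT background by comparing WT_K118R with WT. KRT4, CRNN, MYH11 and IGHG1 were lower with WT_K118R, interferon-stimulated genes were higher, and SPI1 and TUBA1A were near 0. KRT4 had 0 counts against 262, at least 86.2-fold lower, and CRNN was at least 22.7-fold lower. MYH11, the smooth muscle myosin heavy chain, had 1 count against 215, a ratio of 212 (37.7 to 8418). Other keratins, named after their values were seen, went the opposite way, with KRT14 at 135 counts against 28, KRT6A at 176 against 83, KRT5 at 161 against 106 and KRT16 at 38 against 12. SPI1, which encodes the myeloid and B cell factor PU.1, had 1 count against 173, a ratio of 171 (30.2 to 6781), and 113 to 139 counts in the other 3 libraries. Lists of squamous, immunoglobulin, smooth muscle and interferon-stimulated genes also differed between PMSCV and WT, neither labelled K118R. Their sums there were 471 and 1413, 752 and 506, 103 and 385, and 61 and 19 counts. For these lists the substitution cannot be told apart from other differences between the libraries.

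The 18 interferon-stimulated genes entering had a median log2 ratio of 2.79 (100 percentile), with 15 higher and 1 lower. The median was 0.43 with zeros at their bound, and 4.79 and 1.61 with pseudocounts of 0.1 and 5 CPM. All 27 matched members of the list summed to 115 counts against 19, 6.13-fold higher (3.75 to 10.6). Each member had few counts, IFI27 having 7 against 0 and CXCL10 6 against 0. The sum was 4 counts in S_PXT1 and 1 in S_PXT1_K118R. The 10 NF-kB target genes had a median of 2.25 (99.8 percentile), 0.55 with zeros at their bound, with NFKBIA at 49 counts against 3. Heat shock chaperones had a median of 0.36 (99.9 percentile), 0.29 with zeros at their bound, with 3 of 16 higher, among them HSPA1A at 18 counts against 4. Glycolysis and hypoxia genes had a median of 0.25 (98.7 percentile), 0.17 with zeros at their bound, with 6 of 28 higher and 0 lower. Mitosis genes had a median of 0.51 (98.0 percentile), 0.02 with zeros at their bound, and YAP and TEAD targets 0.78 (97.9 percentile), 0.00 with zeros at their bound, and the summed folds were 1.15 (0.97 to 1.36) and 1.26 (0.84 to 1.91). Mitochondrially encoded protein genes had a median of -0.20 (0.94 percentile), -0.13 with zeros at their bound, and a summed fold of 0.96 (0.92 to 1.01). Erythroid and megakaryocyte markers had a median of 2.12 (99.6 percentile), 0.00 with zeros at their bound, on 19 counts against 11.

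Among single genes SPP1, ANO1 and MMP1, genes of secreted or membrane proteins in epithelial and stromal cells, had 18 to 38 counts with WT_K118R and 0 with WT, at least 6.08-fold to 12.8-fold higher. TTC7B, NDUFAB1, PDCD5, TBP and DOCK2 had 20 to 40 counts against 0, of which PDCD5 was at 0 in WT alone. KRT13 had 1 count against 266, a ratio of 262 (46.7 to 10406), and SENP3-EIF4A1, BCL7C, PPL, TGM3 and IGHA1 were at least 10.5-fold to 21.7-fold lower. Among well-covered genes TUBA1A was 52.6-fold lower (29.9 to 102), MATR3 had 15 counts against 545, TAF9 had 7 against 216, and IGHG1 was 23.5-fold lower (12.5 to 49.6). With overlapping models summed the log2 ratio was -0.04 for SENP3-EIF4A1 and -1.11 for MATR3. CITED2 was 4.47-fold lower (3.70 to 5.43), KDM2A 3.65-fold (2.76 to 4.89) and SRSF7 3.59-fold (2.47 to 5.35). HMGB1 was 13.6-fold higher (9.26 to 20.8), YTHDF3 3.52-fold (2.65 to 4.72) and CBX1 2.75-fold (2.13 to 3.58). In all 2559 genes were higher and 2795 lower, against 2003 and 2064 from counting error alone. The interval excluded 1 for 255 higher and 320 lower genes, and at a mean of at least 20 counts 38 were higher and 44 lower, against 6.59.

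The 2 K118R comparisons, which share no library, were set side by side to ask whether the same genes differed with the substitution in both backgrounds. CITED2 was lower with the substitution in both, whereas CBX1 and NFKBIA were lower with S_PXT1_K118R and higher with WT_K118R. Over 13352 genes Pearson's r was -0.004 and Spearman's rho -0.004, across genes, which are not independent replicates. Genes higher in both numbered 442 against 389 for independent lists, genes lower in both 539 against 491, and genes that went opposite ways 975 against 875. At a mean of at least 20 counts 13 genes were lower in both against 2.10 and 4 higher in both against 1.28. Another 10 went opposite ways against 3.30, and Pearson's r was 0.039. This mean is over all 5 libraries, so genes nearly absent from both S_PXT1 libraries can pass it. IGKC and MYH11, among the 13, each had 1 count in S_PXT1 and 0 in S_PXT1_K118R. The largest shared ratios were those of SENP3-EIF4A1, RTF1, VAMP4, PFDN2 and SF3A2, at 0 counts in both K118R libraries, and of TTC7B, NCAPG, POM121C, ID3 and RPL7P14, at 0 counts in both S_PXT1 and WT. TTC7B had 15 and 40 counts in the K118R libraries, and RTF1 19 and 17 counts in the others. The log2 ratio of SENP3-EIF4A1 in the WT background was -0.04 when overlapping models were summed.

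The ratio of S_PXT1 over WT was compared in the same way with that of S_PXT1_K118R over WT_K118R. KRT5 led the shared differences, at 106 and 161 counts in WT and WT_K118R and 0 in both S_PXT1 libraries. KRT6A, KLK3, DSP, CD74, STEAP2, PRUNE2, AP1G2, SERINC5 and SENP6 followed, each at 0 in both S_PXT1 libraries. Pearson's r across genes was 0.23 and Spearman's rho 0.25, and 3231 genes were lower in both against 2497 for independent lists. At a mean of at least 20 counts r was 0.52, with 56 genes lower in both against 8.53 and 8 higher in both against 1.31. At a mean of at least 100 counts r was 0.28, with 6 lower in both against 0.29 and 3 higher in both against 0.14. The number of genes detected divides the libraries in the same way. An effect of the S_PXT1 constructs therefore cannot be told apart from anything else that both S_PXT1 libraries share.

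Each library was finally compared with the other 4 together. Genes at least 2-fold above all others numbered 1028 in PMSCV, 112 in S_PXT1, 129 in S_PXT1_K118R, 721 in WT and 756 in WT_K118R. Genes below all others numbered 234, 940, 1129, 173 and 206 in the same order. SRXN1, NTRK2 and AGTRAP had 8 to 11 counts in PMSCV and 0 elsewhere, and CRNN had 69 counts in WT alone. At a mean of at least 100 counts S_PXT1 stood at least 2-fold above all others for CITED2, GATA2 and LDB1 and WT_K118R for HMGB1, while no gene did so in PMSCV, S_PXT1_K118R or WT. At least 2-fold below all others were 7 genes in WT_K118R, 5 in S_PXT1_K118R, 2 in S_PXT1, RPN2 and TUBA1C, and 1 each in PMSCV, PSME3, and in WT, YTHDF3. As a pair, S_PXT1 and S_PXT1_K118R lay below the other 3 libraries in 2089 genes and above them in 81.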

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

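All tests in this part were chosen after the results were seen. CBX1 differed with the substitution in opposite directions in the 2 backgrounds, with a log2 ratio of -1.40 for S_PXT1_K118R over S_PXT1 and 1.46 for WT_K118R over WT. The difference between the backgrounds was not tested.

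The libraries labelled S_PXT1 and S_PXT1_K118R held fewer genes than the others, 7393 and 7044 against at least 11492, and depth is argued against, since thinned to 250409 counts the lowest of the other 3 still held 10451. A candidate source is human RNA or reads in PMSCV, WT and WT_K118R alone, which the human gene models would count. The whole fixed list of fibroblast, endothelial and epithelial markers, tried first, reached 0.545 of the lowest other level in the pair. Mouse reads counted in all 5 libraries would add to such a source, so this value cannot decide it. The limits for this ratio were also set after the results were seen. The list was split after its members had been seen, so the parts can only raise a hypothesis. The epithelial members EPCAM, KRT8, KRT18 and CDH1 reached 0.0337, a level such a source would give. The fibroblast members reached 0.625, which cannot decide for the same reason as the whole list. Their sum in the pair was carried by COL1A1, COL3A1 and SPARC. The other 5, picked by their values, reached 0.132 and leave the source open. A lower yield of less conserved genes also stays open, and the value first taken for it, the immunoglobulin list at 17.2-fold in WT over WT_K118R, compares libraries outside the pair and decides nothing. An effect of the S_PXT1 constructs cannot be told apart from anything else the pair shares, which differed from the rest in 2170 genes against 1058 for the next pair.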

How the results depend on the processing

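The alternatives at a mean of at least 20 or 100 counts, with intervals that exclude 1, with symbols known in mouse and with overlapping models summed were chosen after the results were seen. There was no replicate to leave out, no replicate number pairs the libraries, and no additive fit of background and substitution was made. The counts of genes past 2-fold stayed within 1.5 times in the 5 comparisons with a pseudocount of 0.1, no filter, DESeq2 size factors, thresholds of 1.5-fold and 3-fold, named genes alone, symbols known in mouse and overlapping models summed. DESeq2 size factors moved the share of higher genes in S_PXT1 over PMSCV from 16.5% to 16.8%. Depth limits the counts of low genes, since a single count was worth at least 2.92 CPM.

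In the order S_PXT1 over PMSCV, WT over PMSCV, S_PXT1 over WT, S_PXT1_K118R over S_PXT1 and WT_K118R over WT, the counts were 7008, 5802, 6878, 4376 and 5354. They were 4563, 3207, 4441, 2081 and 3292 with a pseudocount of 5, and 3569, 2130, 3352, 2502 and 1991 at a mean of at least 5 CPM. With FPKM they were 2828, 1809, 2530, 1790 and 1684. They were 175, 83, 156, 126 and 82 at a mean of at least 20 counts, and 19, 7, 17, 16 and 11 at a mean of at least 100. With an interval that excludes 1 they were 1094, 497, 941, 323 and 575. All of these filters test fewer genes or ask for more, and otherwise the cause was not tested. Cases of a gene in which a library lay apart from the other 4, summed over libraries and both directions, numbered 5428. A gene apart in more than 1 library counts once for each, as CITED2 does at a mean of 100 counts. The cases numbered 2732 with a pseudocount of 5, 8313 with no filter, 2844 at a mean of 5 CPM and 1798 with FPKM. They numbered 139 at a mean of 20 counts and 20 at a mean of 100.

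The correlation of the K118R ratios, -0.004, became 0.039 at a mean of 20 counts. That of the S_PXT1 over WT ratios with and without the substitution, 0.233, became 0.202 with a pseudocount of 0.1, 0.274 with 5, 0.337 with no filter, 0.317 at a mean of 5 CPM, 0.217 with FPKM, 0.519 at a mean of 20 counts and 0.278 at a mean of 100. The cause was not tested. Of 165 ratios of named genes, 6 turned direction, each when overlapping models were summed, because a neighbouring model on the same strand then shares the count. The log2 ratio was -0.52 for SENP3-EIF4A1 in S_PXT1 over PMSCV, and 2.28 for MT-ND4L and 0.39 for BLOC1S5-TXNDC5 in WT over PMSCV. It was -2.85 for MT-ND4L in S_PXT1 over WT, and -0.23 for RBM4 and 1.65 for MT-ND4L in S_PXT1_K118R over S_PXT1. Another 10 named ratios moved beyond their counting interval when overlapping models were summed and 10 with FPKM. Among the latter, the log2 ratio with FPKM was -4.64 for MYH11 in WT_K118R over WT. It was -3.39 for STEAP2 and -2.44 for PRUNE2 in S_PXT1 over PMSCV. Of the 25 list medians outside the middle 95% of random lists, none took the opposite sign under the alternatives run, but 4 moved beyond their interval with a pseudocount of 0.1, 3 with 5 and 1 with no filter. That of p53 targets in S_PXT1 over WT was -5.89 and -1.12 with pseudocounts of 0.1 and 5, and that of interferon-stimulated genes in WT_K118R over WT 4.79 and 1.61. That of mast cell markers in S_PXT1 over PMSCV was -6.17 and -1.28 with the same pseudocounts and -1.09 with no filter, and that of erythroid markers in WT_K118R over WT was 4.94 with a pseudocount of 0.1. With no filter the medians of NF-kB targets and erythroid markers in WT_K118R over WT and of the BCL2 family in S_PXT1_K118R over S_PXT1 were 0.00.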

Other observations

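The tests in this part were chosen after the results were seen, and the 4 added marker lists were made once the ratios were known. Squamous epithelium genes summed to 471 counts in PMSCV, 1413 in WT and 721 in WT_K118R, against 1 in S_PXT1 and 6 in S_PXT1_K118R. Prostate epithelium genes had 237, 241 and 217 counts against 3 and 2, led by KLK3 with 51, 62 and 71 and STEAP2 with 58, 49 and 36. Immunoglobulin genes summed to 752, 506 and 29 counts against 2 and 2, led by IGHG1 with 310, 238 and 10, with IGHM at 6, 3 and 2, and smooth muscle genes to 103, 385 and 39 against 1 and 8, led by MYH11 with 54, 215 and 1. ACTA2 of the smooth muscle list is also in the fixed fibroblast, endothelial and epithelial list.

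In the order PMSCV, S_PXT1, S_PXT1_K118R, WT and WT_K118R, the collagen gene COL3A1 had 132, 73, 95, 155 and 202 counts, SPARC had 64, 42, 47, 60 and 101, and COL1A2 had 90, 3, 4, 68 and 102. Genes at 0 counts in both S_PXT1 and S_PXT1_K118R took 4.22% of the counts in PMSCV, 3.74% in WT and 3.41% in WT_K118R. Genes whose human symbol is not known in mouse, leaving out pseudogenes and clone names, numbered 676, 666 and 603 in those libraries and 243 and 203 in the pair, and genes whose symbol is known in mouse 9074, 9210 and 9081 against 5711 and 5455. The interferon-stimulated list held 61, 19 and 115 counts in PMSCV, WT and WT_K118R against 4 and 1 in the pair. No explanation was tested for that list.

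Of the 1547 genes with a mean of at least 20 counts, 39 were at 10% or less of the median of the 5 libraries in exactly 1 library, of which 17 were in S_PXT1_K118R, 9 in S_PXT1, 6 in PMSCV, 6 in WT_K118R and 1 in WT. In 11 of them, among these IGKC, MYH11 and SERBP1, a second library was also under 25% of the highest, a limit set after the values were seen, which left 28 genes low in a single library, 9, 8, 5, 6 and 0 in the same order, among them SPI1 and TUBA1A in WT_K118R, YTHDF2 in S_PXT1_K118R and RPN2 in S_PXT1. A first definition, near 0 in 1 or more libraries, had given 100 cases and 89 after overlapping models were summed, and it was narrowed after that result was seen because the genes absent from both S_PXT1 libraries filled it. Counting error is argued against, with a mean of 0 such genes over Poisson draws. These draws take reads as independent and leave other variation between libraries untested. Reads passed between overlapping gene models of 1 strand are argued against too, since 34 loci met the limit after summing, or 23 with no second library low. A true loss with a construct and an uneven assignment of mouse reads to human models both stay open and were not tested.

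As a hypothesis, the S_PXT1 construct may raise a set of genes in a way that the substitution removes. Both differences it rests on use the same single S_PXT1 library. CITED2, SRSF10, GATA2, CBX1, LDB1, CPSF6 and KHDRBS1, all with a mean of at least 100 counts, were at least 2-fold higher in S_PXT1 than in PMSCV and at least 2-fold lower in S_PXT1_K118R than in S_PXT1, and 3 of them, CITED2, GATA2 and LDB1, lay at least 2-fold above all 4 other libraries. The median log2 ratio of genes at this coverage was 0.28 in S_PXT1 over PMSCV. Set against that shift, GATA2, KHDRBS1 and SRSF10, at 2.31-fold, 2.19-fold and 2.07-fold, would fall below 2-fold. Counting error gave a mean of 0 genes with both differences over Poisson draws, and all 7 kept both after overlapping gene models of 1 strand were summed. At this coverage 0% of simulated unchanged genes passed even 1 such threshold in S_PXT1 over PMSCV. The draws therefore leave variation between libraries untested. Irregular single libraries remain a candidate explanation, since WT_K118R over PMSCV and S_PXT1_K118R gave 6 genes, the most among 21 choices of another peak library, leaving out those against both S_PXT1 libraries, a limit set after WT_K118R over that pair had given 8. Members also go against a single set, with CPSF6 in S_PXT1 at 1.14 times its level in WT (0.90 to 1.43), CBX1 at 676 CPM in WT_K118R against 706 in S_PXT1, and CITED2 lower with the substitution in the WT background too, so both readings stay open.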
